A study of Mus musculus with 6 samples.

How the data were processed

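Primary myoblasts from skeletal muscle of 1-month-old male mice were expanded in F-10 medium with 20% fetal bovine serum and basic fibroblast growth factor at 2.5 ng/mL, then differentiated for 4 days in 2% horse serum, per the labels' protocols. RNA was extracted on spin columns and polyA RNA was sequenced on an Ion Proton after an Ion Total RNA-Seq library preparation. The group of each of the 6 libraries, Sfpq knockout or control, was taken from its title. The series gives 3 mice per genotype, and nothing in the labels ties a library to a separate mouse or culture, so p-values measure only the spread between these samples, which may be partly technical.

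The values deposited by the authors are TPM, 1 value per RefSeq transcript accession for each library, and they sum to 1000000 per library. Reads were aligned with STAR 2.4.1d and the mm10 genome was used, per the submitters' processing notes. The counting tool, the annotation release and the use of strand are not given in the sources used here, so overlapping and antisense genes are treated as uncertain. TPM keeps no read depth, so no count model was used and no counting interval is given. Of 34671 accessions in each library, 30822 were named through a RefSeq gene table of GRCm38.p6, the assembly that mm10 also holds, and 103 through GENCODE annotation. The other 3746 (10.8%) had no gene name, held 1.19% to 1.27% of TPM and kept their accession as an identifier in the tests. Summing gave 34656 genes. Genomic spans and coordinates, counted from 1, come from the same RefSeq table, and 11956 tested genes had a span.

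Genes with a TPM of at least 1 in at least 3 libraries were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, using the intensity trend, no block and a 2-sided moderated test with Benjamini-Hochberg adjustment at 0.05. Fold changes are differences on that log2(TPM + 1) scale, which understates the change of low genes. Long genes were those of 100 kb or more and were compared with all other genes by limma's camera with a preset correlation of 0.01. The same test was run on 25 of 30 gene lists, those with at least 5 tested members, with adjustment over the lists. Members of a list are also reported with limma's p adjusted over the list alone. Bootstrap intervals resample genes, so they measure the spread between genes and not that between libraries or mice. Exact permutation tests of a list's mean level are 2-sided and cannot give less than 0.1 with 3 against 3. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for joining and plots.

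The tests of genes, long genes and gene lists, the gene lists, the alternatives other than those said below to be added, and the rule for named genes were fixed before the data were examined. Some tests of explanations were chosen after results were seen, as the closing section says. The rule names Sfpq, then up to 12 genes per direction with the largest change among those past the threshold. With fewer than 5 past it, the 5 smallest p in that direction are named instead and said not to pass, which applied in both directions. It adds the 8 lower and 4 higher genes of 100 kb or more with the smallest p, and from each list up to 4 members with the smallest p (up to 3 with the highest TPM for other cell types and sample checks). Genes named outside the rule are members past the test in their list, the Sfpq relatives and, where said, genes picked after their values were seen. Some genes that the rule names are not reported here.

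The gene-level test was run on simulated data with the spread of these libraries before use. For this comparison over 12461 genes it recovered 68.0% of genes with a log2 change of 1 and 86.0% of those with a log2 change of 2. There were 7 false calls, and 4 of 100 unchanged lists fell under 0.05 in camera. With 100 genes changed at each size, the Benjamini-Hochberg cutoff was looser than where few genes change. In the real data Sfpq, at a log2 difference of −1.57, did not pass (limma adjusted p = 0.0531). The shares recovered therefore do not show how many changes of that size the real test missed. The simulated genes varied independently of each other. The camera result therefore cannot show how that test behaves on lists whose members vary together. In the real data the estimated correlation was 0.52 within the oxidative phosphorylation list. Alternatives covered the pseudocount (0.1 and 5), the filter, median-of-ratios and quantile scaling, rescaling without ribosomal protein and histone genes, limma without trend or with robust moderation, a replicate block, each library left out, an adjusted p under 0.1, span thresholds of 50 and 200 kb, an estimated correlation in camera and expression-matched shorter genes as background. The rescaling was also meant to leave out mitochondrially encoded genes, but none was found by name in the deposited values. Spans from GENCODE, protein-coding genes alone and the 200 kb threshold under each alternative were added after seeing the data. In the alternatives, an uncalled gene whose sign changed was counted as reversed only if its log2 difference exceeded its SE.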

Results

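Messenger RNA was profiled in muscle cell cultures from mice with a knockout of Sfpq in skeletal muscle and from control mice. Sfpq is a nuclear RNA-binding protein that takes part in transcription, splicing and the formation of paraspeckles, which are nuclear bodies built on the long noncoding RNA Neat1. Primary myoblasts, the muscle precursor cells, were grown from skeletal muscle of 1-month-old male mice, expanded with fibroblast growth factor and kept for 4 days in 2% horse serum, a low-serum medium in which myoblasts leave the cell cycle and fuse into myotubes. The 6 libraries fall into 2 groups, Sfpq knockout (n = 3) and control (n = 3). Each library held between 12216 and 12484 genes at a TPM (transcripts per 1000000 transcripts) of 1 or more, and 12461 genes entered the tests. TPM values keep no record of read depth, so the depth behind each value is unknown. The cultures were differentiated muscle by their leading transcripts: the skeletal actin Acta1 or the noncoding RNA H19 was the most abundant gene in each library, and the 10 most abundant genes held 13.2% to 17.5% of all TPM. The series' title asks whether long genes in particular depend on Sfpq, so the genotypes were compared gene by gene, by the genomic span of each gene, and over gene lists for muscle, metabolism and stress.

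Sfpq itself (chromosome 4, 127020716 to 127051101 in GRCm38) stood at 17.2 ± 2.78 TPM in the knockout libraries and at 53.01 ± 6.50 TPM in the control libraries (SD, n = 3), with each knockout library below each control library. The log2 difference was −1.57 (SE 0.15), and the mean TPM was 3.08 times as high in control. Its span overlaps Zmym1 on the opposite strand, and which exons the knockout removes is not given in the sources used here. Its paralog Pspc1, a paraspeckle protein of the same family, showed the opposite difference, 29.7 ± 1.64 TPM in knockout against 15.7 ± 2.35 TPM in control (log2 difference 0.89, SE 0.12). Nono, the other member of the family, was near equal at 99.5 ± 4.73 and 98.6 ± 20.6 TPM. No gene passed the genome-wide test: limma with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower, and the smallest adjusted p was 0.0531, shared by Sfpq, Cep295nl, E130307A14Rik, Vti1a, Srsf4 and Fgf13. At an unadjusted p under 0.05 there were 334 genes higher and 1199 lower in knockout. That split shifted to 787 higher and 657 lower after median-of-ratios scaling and to 694 and 677 after quantile normalization. The median log2 difference of all genes was −0.07 on the deposited scale and 0.01 and 0.00 after these scalings. Groups that did not overlap were found for 532 genes higher (4.27%) and 1906 lower (15.3%), where chance gives 5% in each direction on average over splits of the libraries. These shares were computed on the deposited scale alone, where the median lies below 0. Sfpq and a few others passed with a pseudocount of 5, which called 2 genes higher and 11 lower, and with a mean TPM of 5 or more, which called 1 and 6. Without control replicate 2 the unadjusted counts were 615 and 1266, and without control replicate 3 they were 256 and 650.

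**Figure D1:**
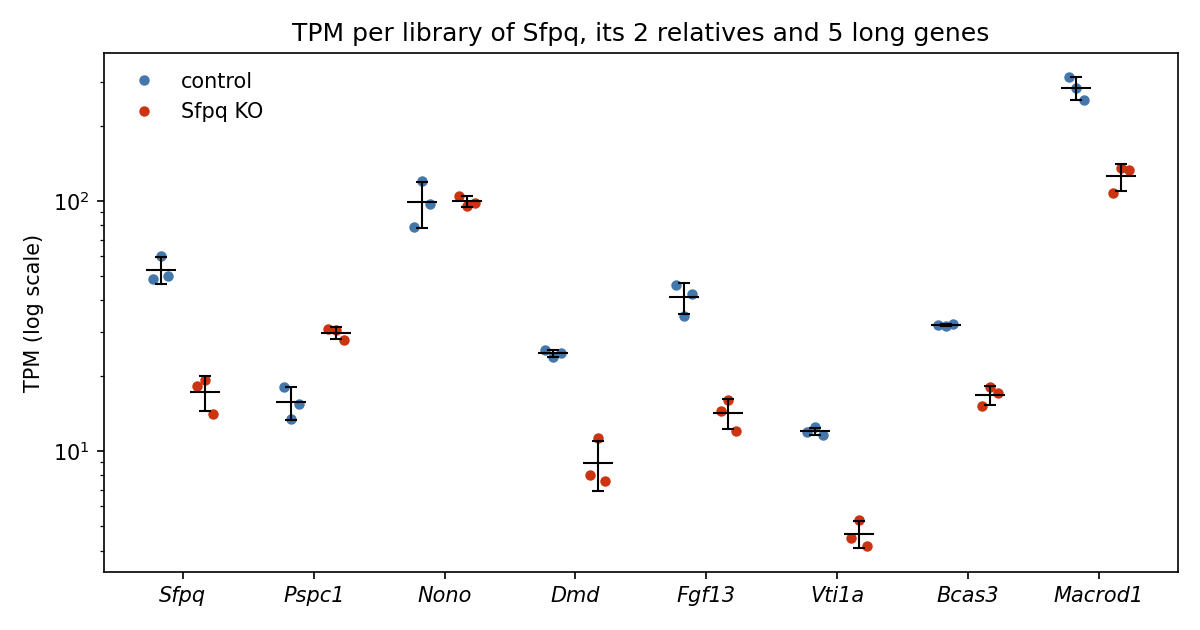
TPM per library on a log scale (y axis) for Sfpq, its relatives Pspc1 and Nono, and 5 long genes (x axis), in control (blue) and Sfpq knockout (red) libraries; points are libraries and black bars give the mean ± SD, n = 3 per group. Sfpq averages 17.2 TPM in knockout and 53.01 in control, Nono is near equal in both, and the 3 knockout libraries lie below the 3 control libraries for each of the long genes.

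The genes nearest to the threshold on the lower side included long genes and a splicing factor. Vti1a, a SNARE protein of vesicle transport (chromosome 19, 55316030 to 55627461), was at 4.65 ± 0.57 TPM in knockout and 11.98 ± 0.42 TPM in control. Fgf13, an intracellular regulator of sodium channels (chromosome X, 59062139 to 59585572), was at 14.2 ± 1.95 against 41.2 ± 5.84 TPM. Srsf4, a serine and arginine rich splicing factor, was at 24.3 ± 0.77 against 44.0 ± 2.22 TPM. E130307A14Rik, a gene of 111 kb, was at 2.41 ± 0.09 against 7.67 ± 0.85 TPM, and its span overlaps Traf3ip2 on the opposite strand. On the higher side, Cep295nl was at 4.19 ± 0.42 against 0.66 ± 0.18 TPM, but it lies within the span of Timp2 on the same strand, so reads of the pair may not be separable. Pea15a, a phosphoprotein linked to apoptosis and ERK signalling, was at 88.5 ± 10.8 against 45.6 ± 4.83 TPM with Dcaf8 overlapping on the opposite strand, and Alox12, a lipoxygenase, at 3.95 ± 0.06 against 1.62 ± 0.11 TPM. Uap1l1 stood at 71.0 ± 1.37 and 43.6 ± 0.71 TPM, and Tceal3, a member of a multigene family with similar sequences, at 105 ± 17.0 and 50.4 ± 4.38 TPM. Over these 5 higher genes the adjusted p of the limma test ran from 0.0531 to 0.0900, so none passed.

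Long genes were lower in the knockout libraries, and more so the longer the gene. The 1415 genes with a span of 100 kb or more had a median log2 difference of −0.14, against −0.06 for the 10541 shorter genes. From the shortest to the longest bin the median went from −0.02 (under 10 kb, 3255 genes) through −0.07 (10 to 50 kb), −0.10 (50 to 100 kb) and −0.12 (100 to 200 kb) to −0.20 (200 kb or more, 484 genes, 95% bootstrap interval over genes −0.22 to −0.17). Among genes of 200 kb or more, 34.1% had all knockout libraries below all control libraries and 1.24% the reverse. Chance gives 5% each on average over splits of the libraries, and the highest share in another split was 12.2%. All tested genes leaned the same way, with 15.3% separated lower and 4.27% higher, and the share separated lower was 9.65% under 10 kb, 15.2% at 10 to 50 kb, 18.8% at 50 to 100 kb and 21.9% at 100 to 200 kb. The difference of −0.075 between long and shorter genes passed limma's camera test with a preset correlation (p = 0.000212), and with an estimated correlation it did not (p = 0.365). Without control replicate 2 the difference was −0.029 and the camera call was lost, with a p of 0.0980. At a threshold of 200 kb the difference was −0.13, and −0.10 without that library, while a pseudocount of 5 or no filter on low values brought the 100 kb difference to −0.04. In the same libraries transcripts of replication-dependent histone genes had a median log2 difference of 0.22 (camera adjusted p = 6.88e-11, and adjusted p = 0.408 with an estimated correlation), and 0 members passed singly. Most such transcripts carry no polyA tail, and which forms of them these polyA libraries counted was not tested.

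**Figure D2:**
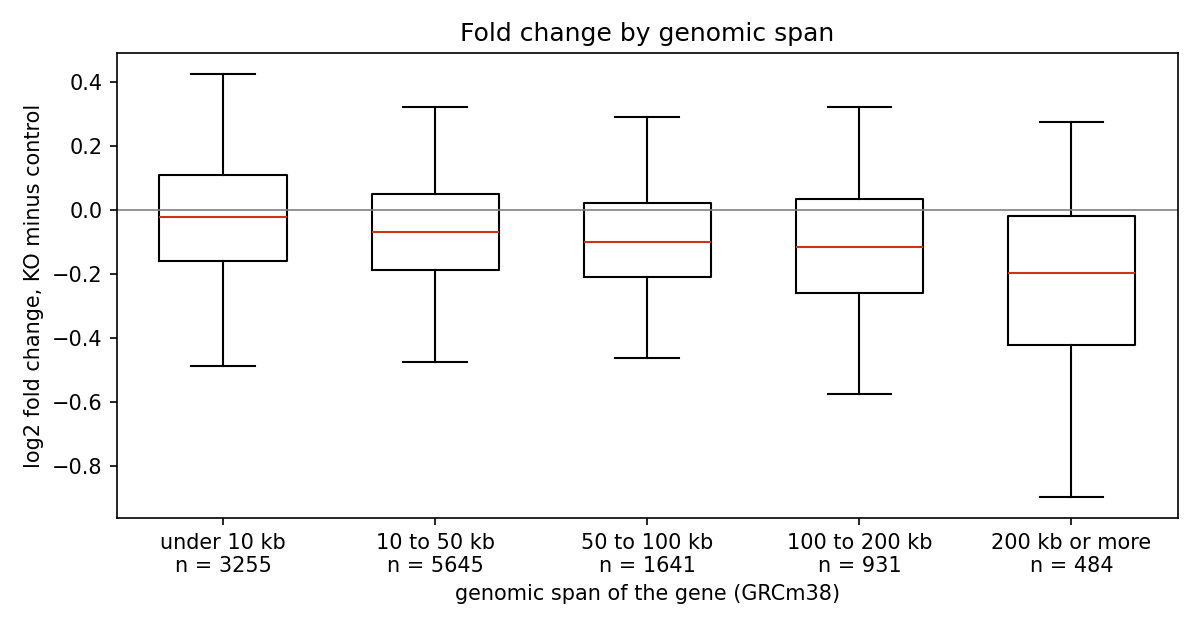
Log2 fold change, knockout minus control (y axis), of tested genes in 5 bins of genomic span in GRCm38 (x axis, with the number of genes); boxes run from the 25th to the 75th percentile, red lines mark medians and whiskers the 5th and 95th percentiles. The medians go from −0.02 under 10 kb to −0.20 at 200 kb or more.

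Among single long genes, dystrophin showed one of the clearest differences. Dmd, which encodes the protein that ties the cytoskeleton to the muscle cell membrane and spans 2390 kb (chromosome X, 82814664 to 85205050), stood at 8.95 ± 2.03 TPM in knockout and 24.5 ± 0.73 TPM in control, a log2 difference of −1.38 (SE 0.15). Macrod1, a mitochondrial hydrolase (chromosome 19, 7056728 to 7198062), was at 125 ± 15.6 against 283 ± 30.7 TPM. Bcas3 (chromosome 11, 85353110 to 85826058) was at 16.7 ± 1.45 against 31.9 ± 0.24 TPM, and Gphn, the scaffold protein gephyrin, at 8.27 ± 0.65 against 17.5 ± 1.91 TPM. The noncoding gene 2610035D17Rik was at 1.71 ± 0.33 against 5.30 ± 0.60 TPM. Over all genes these 5 had adjusted p values of 0.0538 to 0.0704 in limma and did not pass. The spans of Vti1a, Macrod1 and Dmd each overlap a protein-coding gene on the opposite strand. The overlaps named above for other genes are likewise protein-coding ones. Bcas3 and Gphn each overlap 6 annotated genes, Fgf13 4 and Srsf4 2, with 0 protein-coding among them. The long genes nearest to the threshold on the higher side were Rin3 (log2 difference 1.38), Slc24a4 (1.01), Septin9 (0.43) and Nfatc2 (0.82), with adjusted p from 0.143 to 0.264.

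In the list of long genes fixed by name, 40 of 46 tested members had lower values in knockout, and 18 of them fell when limma's p was adjusted over the list alone, against 0 over all genes tested. The list's median log2 difference was −0.36 (camera adjusted p = 6.88e-11, and adjusted p = 0.408 with an estimated correlation). Dmd and Vti1a were among the 18, as was Immp2l, a mitochondrial inner membrane peptidase subunit (3.95 ± 0.98 against 14.1 ± 3.06 TPM). The mean level of the list was below control in each knockout library, and an exact permutation test over the 6 libraries gave p = 0.1, the smallest that 3 against 3 allows. Other members were near equal, such as the dystrophin relative Utrn (19.1 ± 3.31 and 20.1 ± 9.10 TPM) and titin, Ttn (34.2 ± 4.35 and 34.5 ± 0.77 TPM), both picked after their values were seen.

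Genes of energy metabolism were lower in knockout across several pathways. Of the nuclear genes for oxidative phosphorylation, 48 of 49 had lower values, the median log2 difference was −0.27, and 11 fell adjusted over the list alone, among them Cycs, cytochrome c (84.4 ± 11.4 against 124 ± 12.1 TPM), Cox7a1, the muscle form of a cytochrome oxidase subunit (187 ± 35.2 against 401 ± 118 TPM), and the ATP synthase genes Atp5o and Atp5c1. In the tricarboxylic acid cycle, 23 of 23 genes were lower (median −0.33) and 9 fell adjusted over the list alone, including Pdha1 and Pdhb of pyruvate dehydrogenase, Fh1, and Suclg2, a long gene of 246 kb (11.7 ± 1.37 against 17.8 ± 0.83 TPM). For glycolysis and glycogen metabolism, 25 of 26 were lower (median −0.37), and Phkb, a subunit of phosphorylase kinase (43.9 ± 3.24 against 68.8 ± 3.12 TPM), Hk1 and Gpi1 fell adjusted over the list alone. Phkb (223 kb) and Hk1 (111 kb) are themselves long genes, while Gpi1 spans 29.0 kb. Of the genes for fatty acid uptake and oxidation, 21 of 26 were lower (median −0.26) and 1 fell adjusted over the list alone: Acsl1, which activates long-chain fatty acids (72.0 ± 10.7 against 119 ± 16.0 TPM). Over all genes tested, 0 members of these lists passed in limma. The camera test called all 4 lists (adjusted p 1.05e-10, 4.06e-08, 1.09e-06 and 0.00114 in the order given). With an estimated correlation it called none of them (adjusted p = 0.408 for the first 3 and adjusted p = 0.529 for fatty acids), and without Sfpq knockout replicate 1 the fatty acid list missed the threshold (median −0.20, adjusted p = 0.0709). Over 16 other alternatives the size of the difference varied. Taken from the median of all genes, it ran from −0.30 to −0.13 for oxidative phosphorylation. It ran from −0.38 to −0.15 for the tricarboxylic acid cycle and from −0.47 to −0.18 for glycolysis.

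The regulators of these pathways, grouped as the AMPK and PGC-1 axis, were lower as well: 19 of 22 had lower values, with a median log2 difference of −0.22 (camera adjusted p = 0.00666, and adjusted p = 0.408 with an estimated correlation). Adjusted over the list alone 4 fell, all of them estrogen-related receptors or PGC-1 coactivators that drive mitochondrial genes. Each of the 4 is also a long gene, with a span of 100 kb or more. Esrrb went from 25.6 ± 7.14 TPM in control to 6.16 ± 1.89 in knockout, Esrrg from 3.71 ± 0.80 to 1.55 ± 0.15, Ppargc1b from 8.96 ± 0.44 to 5.88 ± 0.90 and Ppargc1a from 6.82 ± 0.70 to 4.80 ± 0.36 (n = 3 each). No kinase subunit of AMPK passed. The call was lost without Sfpq knockout replicate 2 (median −0.16, adjusted p = 0.0855), and the median was −0.14 after median-of-ratios scaling.

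**Figure D3:**
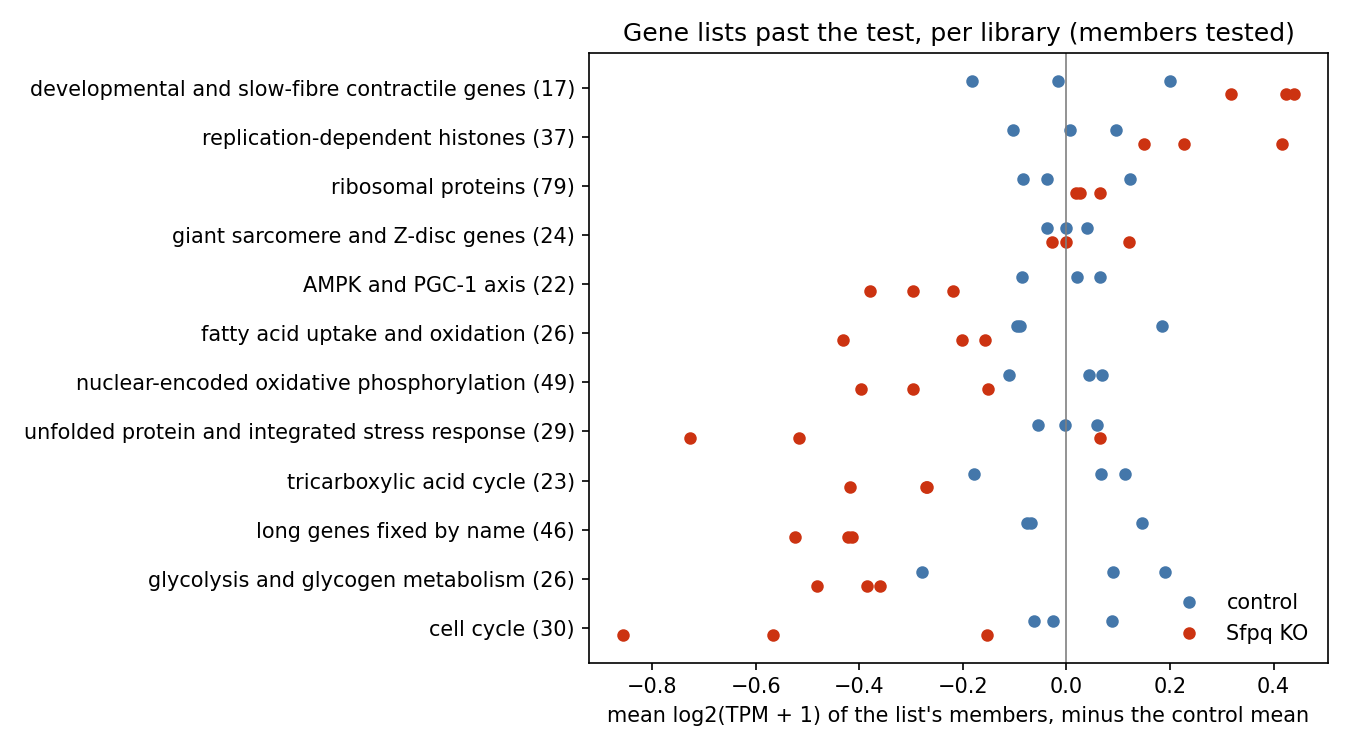
Mean log2(TPM + 1) of the members of each of 12 gene lists past the camera test, minus the control mean (x axis), with 1 point per library, control in blue and Sfpq knockout in red; the number of tested members stands after each list's name. The long genes fixed by name, cell cycle, AMPK and PGC-1 and the 4 metabolic lists have all knockout points below all control points, and the developmental and slow-fibre and histone lists have them above.

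Developmental and slow-fibre contractile genes were higher in knockout: 15 of 17 had higher values and the median log2 difference was 0.36 (camera adjusted p = 2.98e-07, and adjusted p = 0.161 with an estimated correlation), although 0 passed singly, over the list alone or over all genes. Tnnc1, slow troponin C, stood at 6528 ± 221 against 4730 ± 647 TPM, Myl2, the slow regulatory light chain, at 811 ± 366 against 289 ± 188 TPM, and Myoz2 at 335 ± 24.0 against 243 ± 56.4 TPM. For adult and fast-fibre genes the median was −0.25 with 12 of 17 lower, and the list did not pass (adjusted p = 0.641). It passed in 2 of 16 alternatives, without control replicate 2 (median −0.44, adjusted p = 0.0115) and after quantile normalization (median −0.27, adjusted p = 0.0183). Its median depended on single libraries: without control replicate 1 it was −0.05, above that of all genes by 0.048, and without Sfpq knockout replicate 2 it was −0.14. Its member Myh1, the fast IIx myosin heavy chain, fell adjusted over the list alone, from 6335 ± 1956 TPM in control to 2832 ± 201 TPM in knockout. The giant sarcomere and Z-disc genes were split 13 above and 11 below 0. That list's median of 0.05 lay above that of all genes and passed narrowly (adjusted p = 0.0479, and adjusted p = 0.408 with an estimated correlation), and it was lost in 6 of 16 alternatives. The alternatives that ended it included leaving out Sfpq knockout replicate 1 (median 0.04, adjusted p = 0.183), control replicate 2 (median 0.05, adjusted p = 0.180) or control replicate 3 (median 0.04, adjusted p = 0.0859). Without control replicate 1 its median was 0.02. After median-of-ratios scaling it was 0.14, with that of all genes at 0.01.

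Among membrane and calcium-handling genes single members passed but the lists did not. The mean levels of the dystrophin complex and excitation-contraction coupling lists still lay below each control library in each knockout library. For both lists the exact permutation test gave p = 0.1, the smallest possible, as for the long genes fixed by name. In the dystrophin complex and sarcolemma list (22 tested, median −0.05, adjusted p = 0.641) Dmd fell adjusted over the list alone and 21 members did not pass. In excitation-contraction coupling (23 tested, median −0.15, adjusted p = 0.172) 3 members fell adjusted over the list alone: Asph, whose locus encodes junctin (5.22 ± 0.74 against 10.5 ± 0.84 TPM), the calcium channel subunit Cacna2d1 (47.7 ± 3.52 against 81.3 ± 12.1 TPM) and the sodium channel Scn4a (56.3 ± 4.02 against 72.8 ± 2.28 TPM). Asph spans 220 kb and Cacna2d1, also a member of the fixed long-gene list, 440 kb, so both are long genes, while Scn4a spans 48.0 kb. This list passed in 2 of 16 alternatives, without Sfpq knockout replicate 3 (adjusted p = 0.0426) and after quantile normalization (adjusted p = 0.0359), and without Sfpq knockout replicate 2 its median of −0.07 lay only −0.0055 from that of all genes. The myogenic regulators and fusion genes did not pass (18 tested, median 0.06, adjusted p = 0.185), nor did any member. Myf5 stood at 23.5 ± 10.8 and 36.2 ± 3.42 TPM, Pax7 at 13.9 ± 2.44 and 18.4 ± 2.80 TPM, and Des, the muscle intermediate filament desmin, at 6549 ± 720 and 5283 ± 259 TPM in knockout and control.

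Cell cycle genes were lower in knockout, with a mean summed TPM of 187 in knockout and 246 in control over the 30 tested. Of 30 tested cell cycle genes 29 had lower values, with a median log2 difference of −0.55 (camera adjusted p = 1.65e-07, and adjusted p = 0.408 with an estimated correlation). None passed singly. Foxm1 stood at 1.27 ± 0.41 against 2.65 ± 0.54 TPM, Plk1 at 1.91 ± 0.72 against 3.77 ± 0.64 TPM and Mki67 at 0.66 ± 0.51 against 1.71 ± 0.22 TPM. The median was −0.36 without Sfpq knockout replicate 1 and −0.26 with a pseudocount of 5. With members at a mean TPM of at least 5 alone it was −0.29 (camera adjusted p = 0.0304). Transcripts of replication-dependent histone genes went the other way with 32 of 37 higher (median 0.22, adjusted p = 6.88e-11, and adjusted p = 0.408 with an estimated correlation). Whether the forms counted in polyA libraries follow proliferation was not tested. H2bc4 was at 167 ± 27.7 against 109 ± 16.8 TPM, with 0 members past the test singly. The histone median was 0.12 with a pseudocount of 5 and 0.38 at a mean TPM of at least 5. Ribosomal protein genes lay slightly above the other genes, with 60 of 79 higher (median 0.06, adjusted p = 1.09e-06, and adjusted p = 0.555 with an estimated correlation). Their median was 0.03 without Sfpq knockout replicate 1, 0.13 without control replicate 2, 0.01 without control replicate 3 and 0.14 after median-of-ratios scaling.

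Stress-response genes were lower in part of the knockout libraries. In the unfolded protein and integrated stress response list 28 of 29 members had lower means (median −0.29, camera adjusted p = 0.00170, and adjusted p = 0.545 with an estimated correlation). Sfpq knockout replicate 2 lay with the controls, at a mean log2 level of 6.43 against 6.31 to 6.42. Without it the median was −0.48, and without Sfpq knockout replicate 1 it was −0.19. No member passed. Mthfd2, a mitochondrial folate enzyme, stood at 70.5 ± 30.8 against 137 ± 20.4 TPM, Phgdh, the first enzyme of serine synthesis, at 124 ± 48.3 against 212 ± 35.2 TPM, and the transcription factor Atf4 at 340 ± 55.8 against 433 ± 12.4 TPM.

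Several other lists did not pass the camera test. Among paraspeckle and DBHS proteins (18 tested, adjusted p = 0.459) Pspc1 rose and Rbmx, an RNA-binding protein, fell adjusted over the list alone, the latter from 15.1 ± 1.07 TPM in control to 9.89 ± 1.02 in knockout. The p53 targets as a group did not pass (24 tested, median 0.02, adjusted p = 0.149), but Perp, a desmosomal and apoptosis-related gene, rose adjusted over the list alone from 0.21 ± 0.15 to 3.43 ± 2.04 TPM. Atrophy and autophagy genes had a median of −0.11 (21 tested, adjusted p = 0.543) and cholesterol synthesis genes a median of −0.13 (22 tested, adjusted p = 0.336), with 0 members past the test in either. Interferon response genes had a median of −0.13 (11 tested, adjusted p = 0.688). Immediate early genes had a median of −0.10 (17 tested, adjusted p = 0.641), although the camera test placed them on the higher side.

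Markers of other cell types did not pass between the genotypes. Fibroblast and matrix genes had a median of −0.08 (16 tested, adjusted p = 0.713, on the higher side in camera). Sparc stood at 757 ± 138 and 755 ± 166 TPM and Gsn at 266 ± 26.4 and 267 ± 54.0 TPM in knockout and control, and differentiated muscle also expresses both. This list passed on the lower side without control replicate 1 (median −0.48, adjusted p = 0.0429), as did the immediate early genes (adjusted p = 0.0359). Smooth muscle and pericyte genes had a median of −0.20 (10 tested, adjusted p = 0.641) and adipocyte genes −0.14 (7 tested, adjusted p = 0.713, on the higher side in camera). Too few endothelial (4), Schwann cell (3) and leukocyte (1) markers were expressed for a test. Egfl7, Erbb3 and Laptm5, the most abundant of each, stood at 11.3 ± 4.45, 71.5 ± 12.4 and 1.01 ± 0.58 TPM in knockout and at 13.7 ± 5.95, 66.1 ± 19.1 and 1.68 ± 1.19 TPM in control. The Y-linked genes Eif2s3y, Ddx3y and Kdm5d, from a list of 4 tested sex-linked transcripts, were near equal, for instance 58.7 ± 3.47 and 55.0 ± 9.31 TPM for Eif2s3y. No mitochondrially encoded transcript was found by name in the deposited values, so 0 entered the tests.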

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

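Spans from GENCODE and protein-coding genes alone were added after the long-gene result was seen. With a pseudocount of 5 limma called 2 genes higher and 11 lower, with a mean TPM of 5 or more 1 and 6, without trend 1 and 1, and at an adjusted p under 0.1 it called 7 and 21. The mean TPM filter tests fewer genes. The cause of the other changes was not tested. Sfpq passed at −1.39 with the pseudocount of 5 and at −1.57 with the mean TPM filter, while over its alternatives its adjusted p ran from 0.0431 to 0.298. Leaving out 1 library each time gave 0 genes higher and 0 lower in each case, −1.44 to −1.66 for Sfpq and 10 to 14 lists past the test.

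The difference between long and shorter genes stayed below 0 in each alternative. It ran from −0.029 without control replicate 2, where the call was lost and the cause was not tested, to −0.11 without Sfpq knockout replicate 1. It was −0.06 at 50 kb, −0.13 at 200 kb, −0.07 with spans from GENCODE and −0.07 in protein-coding genes. With an estimated correlation the difference of −0.075 and all 12 lists lost their calls (0 lists past the test). Correlation between members does not account for all of these losses. The giant sarcomere and Z-disc list had an estimated correlation of 0.0060, below the preset 0.01. Its adjusted p in camera still went from 0.0479 to 0.408. The developmental and slow-fibre list, at an estimated 0.015, went from 2.98e-07 to 0.161. What else changed the calls was not tested. At 200 kb the difference ran from −0.03 with no filter on low values to −0.17 without Sfpq knockout replicate 1 and kept its call in the 16 alternatives run at that threshold, which did not include an estimated correlation.

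Of 1887 values of named genes under alternatives, 1845 kept their sign and 17, in 9 genes, passed the test. The 42 with another sign fell in 15 genes, most of them markers of other cell types near 0. Klf2 ran from −0.40 without Sfpq knockout replicate 3 to 0.0091 without Sfpq knockout replicate 2, and the cause was not tested. Of 421 list values, 29 in 9 uncalled lists changed sign. Cholesterol synthesis genes passed without control replicate 3 (adjusted p = 0.0430).

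The shared replicate numbers showed no sign of pairing the libraries. The labels do not say whether they mark a litter or a day, and the correlations below cannot settle it. The deviations of same-numbered libraries correlated at −0.260, −0.247 and 0.0487, and Sfpq knockout replicate 1 correlated best with control replicate 2 (0.412). With the replicate number as a block limma called 0 genes higher and 0 lower (224 and 835 at an unadjusted p under 0.05), Sfpq stood at −1.57 (adjusted p = 0.296) and 11 lists passed. The difference for long genes was −0.075 in that fit, with a camera p of 0.000186. The giant sarcomere list was the one lost (adjusted p = 0.0609). Since TPM holds no depth, how far depth limits low genes is unknown.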

Other observations

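The tests of mRNA length, of fewer differentiated cells, of the metabolic genes' span and scaling, of long members in the AMPK and PGC-1 list, and of how often other splits match the long-gene difference and the gene counts, were chosen after those results were seen.

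More of the fixed long-gene list than the report names fell adjusted over the list alone, in genes with varied roles; these and the genes below were picked after their values were seen. The cadherin Cdh13 stood at 102 ± 26.0 TPM in knockout and 239 ± 36.4 in control (log2 difference −1.24), Wwox, which spans 913 kb, at 5.63 ± 0.84 and 16.2 ± 4.10 (−1.35), and the growth hormone receptor Ghr at 27.3 ± 3.21 and 45.0 ± 1.57 (−0.70). Outside the lists Col23a1, a transmembrane collagen of 294 kb, had the largest lower value among genes of at least 5 TPM with separated groups and an unadjusted p under 0.01, 2.04 ± 1.70 against 23.9 ± 12.7 TPM (−3.05, limma adjusted p = 0.108). Single enzymes with lower values that did not pass, which stand for no tested group, were the aminotransferase Got1 at 150 ± 25.9 against 354 ± 82.8 TPM, the malic enzyme Me3 at 9.71 ± 2.51 against 24.4 ± 1.21 TPM, the isocitrate dehydrogenase Idh1 at 28.1 ± 0.52 against 44.0 ± 2.08 TPM and pyruvate carboxylase, Pcx, at 43.4 ± 4.16 against 66.1 ± 3.88 TPM.

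Short genes stood out as well. The deiodinase Dio2, which activates thyroid hormone, was at 9.42 ± 4.58 TPM in knockout and 32.4 ± 7.22 in control (−1.75), and the interferon-inducible GTPase genes Gbp6 (18.2 ± 4.93 and 71.5 ± 36.5 TPM) and Gbp10 (13.3 ± 3.90 and 48.1 ± 24.1 TPM), which belong to a family of near-identical copies, were lower, though the fixed interferon list did not pass. Higher in knockout were the keratin Krt80 (20.3 ± 7.82 and 3.95 ± 2.53 TPM, 2.15) and Fgfbp1, a carrier of fibroblast growth factors (38.4 ± 16.1 and 9.85 ± 3.70 TPM, 1.82). None of these passed limma over all genes.

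For the lower level of long genes, degraded or size-selected RNA would act through mRNA length. Within tertiles of mRNA length long genes lay −0.19 from the others among the shortest mRNAs (95% bootstrap interval over genes −0.27 to −0.08) and −0.11 in the middle tertile (−0.15 to −0.072). Among the longest, which hold 903 of the long genes, they lay −0.035 from the others (−0.052 to −0.016). Of the 3 GC tertiles the smallest difference was −0.049 (−0.071 to −0.023). Long genes were lower within each tertile, which argues against mRNA length or GC content as the sole cause, but the tertiles are broad. Among the shorter genes alone the median rose with GC, from −0.11 through −0.07 to −0.01. It fell with mRNA length, from −0.03 through −0.06 to −0.09. A part played by mRNA length or GC content is therefore not excluded. Low expression of long genes does not account for their lower level, as their median lay −0.066 from that of expression-matched shorter genes (−0.077 to −0.055), below each of 1000 draws. Fewer differentiated cells cannot be told apart from it: the pooled median of contractile and sarcomere genes was 0.21 above that of the long genes (0.09 to 0.37), but it joins slow-fibre genes at 0.36 with fast-fibre genes at −0.25 and so decides nothing. Of the 10 splits of the 6 libraries, too few for a share under 0.05, 3 gave a difference as far from 0 as the real one (highest other 0.107). At 200 kb the difference was 0.132 in size against 0.131 in another split. The 34.1% of genes of 200 kb or more separated in 1 direction (highest other 12.2%) was reached by 1, the real split. So were the 18 fixed long genes past the test (highest other 0). A role of Sfpq in transcribing long genes and shared variation between cultures therefore both remain open. The camera p of 0.365 with an estimated correlation between genes does not decide between them. Lists with little estimated correlation lost their calls as well.

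Metabolic genes may be lower because they are long themselves, but the median span of the 124 members with a span was 15.2 kb, and the 111 under 50 kb lay −0.24 from other genes under 50 kb (bootstrap interval over genes −0.27 to −0.21). Scaling of TPM to a fixed sum is argued against by the pooled median after median-of-ratios scaling, −0.22 (−0.25 to −0.18). The mean level of the members differed by 0.312 between the genotypes, against at most 0.266 in the other splits, so 1 of 10 was as large, which is too few splits for a share under 0.05. Control replicate 2 (8.10) lay nearer to Sfpq knockout replicate 3 (8.03) than to control replicates 1 and 3 (8.30 and 8.36). Control replicates 1 and 3 were also highest on the first principal component described below, and Sfpq knockout replicate 1 was lowest on each. The state of each culture therefore cannot be told apart from genotype here. A hypothesis that joins the long-gene and metabolic patterns is that long regulators are lost and short metabolic genes follow. It is untested: in the AMPK and PGC-1 list the 6 members of 100 kb or more had a median −0.30 from that of the 16 shorter members (permutation p = 0.0490), but this split was chosen after the 4 members that fell, all of that length, had been seen, so it restates the long-gene pattern and cannot tell whether other genes follow.

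The main axis of variation between libraries did not separate the genotypes, though it leaned with them. On it Sfpq knockout replicates 1 to 3 stood at −26.0, 0.59 and −10.1, and control replicates 1 to 3 at 32.0, −12.5 and 15.9. The first principal component held 39.9% of the variance and put Sfpq knockout replicates 1 and 3 and control replicate 2 on one side. That same split gave 1779 genes at an unadjusted p under 0.05 and called 3 genes, against 1533 and 0 for the genotype split. A high count for it is partly built in, because the component was drawn from the same values. The comparison therefore does not show what sets the libraries apart. The component may reflect how far each culture had differentiated or stopped dividing. The 4 lists set against it held no metabolic list. Over the 6 libraries the largest correlation of these 4 was with adult and fast-fibre genes (Pearson r = 0.807, exact permutation p = 0.0472, adjusted 0.0963, and Spearman rho = 0.60, p = 0.242, adjusted 0.322). Without the 2 libraries farthest from the median that r was −0.62, so it rests on them. The giant sarcomere and Z-disc list had r = −0.798 (exact permutation p = 0.0514, adjusted 0.0963) and rho = −0.943 (p = 0.0167, adjusted 0.0667) with r = −0.58 without its 2 farthest libraries, and the cell cycle list r = 0.776 (p = 0.0722, adjusted 0.0963), rho = 0.657 (p = 0.175, adjusted 0.322) and 0.59, so these kept their sign, while developmental and slow-fibre genes, which went the other way from fast-fibre genes, had r = −0.358 (p = 0.489, adjusted 0.489), rho = −0.371 (p = 0.497, adjusted 0.497) and −0.76; no list passed after adjustment and the explanation stays open.

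With 0 genes called in each direction, 10 of 10 splits reach those counts by construction, so that comparison says nothing about chance (highest other 3). Of the 10 splits 2 gave as many genes at an unadjusted p under 0.05, and 3 gave as many as the 12 gene lists past the test (highest other 12), and 10 splits cannot give a share under 0.05. Genes within 10 Mb of Sfpq, where a strain difference linked to the targeted locus would show, were not enriched at an unadjusted p under 0.01 (7 of 224 against 433 of 11731, Fisher's exact odds ratio 0.842, 95% interval 0.332 to 1.78).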
